A study of Mus musculus with 10 samples.

How the data were processed

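RNA was measured in microglia, the resident macrophages of the brain parenchyma, sorted by flow cytometry from C57BL/6 mice into cells with and without surface CD11c. CD11c is the integrin alpha X chain encoded by Itgax. The 10 libraries fell into 4 groups, with 3 CD11c+ and 3 CD11c− libraries at postnatal day 5 (P5) and 2 CD11c+ and 2 CD11c− libraries at 9 months. Per the labels' protocols, total RNA was purified with a column kit, and the 9-month libraries were made with the SMART-Seq v4 kit for small amounts of RNA. The kit is stated for those libraries only, and the others are described only as made by standard Illumina methods. Age and library preparation were therefore treated as confounded, and no difference between ages within a subset was tested. Only the difference between ages of the CD11c+ to CD11c− fold change was tested, and a subset-specific effect of the kit would enter that difference as well. The labels do not say whether the replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

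The authors deposited raw read counts per gene, as whole numbers, for 49315 genes in each library. Per the submitters' processing notes, the tools used were Trimmomatic 0.36, STAR 2.5.2b and Subread 1.5.2. The genome build, the strand setting and the handling of multiply mapped reads were not given in the sources used here. Of the 49056 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 44858 (91.4%) had the same start and end in the deposited count tables, and 49029 lay on the same chromosome within 100 kb. Coordinates in the text are those of the deposited tables. Gene symbols were taken from that annotation for 49056 identifiers, of which 148 share their symbol with another identifier. Because strand use was not stated, antisense and overlapping genes cannot be told apart, and members of near-identical families such as Ear6, Prg3, the Ifi and the H2 genes may have shared or lost reads. No column of per-sample values was left unused (0 columns).

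Total counts per library ranged from 11892082 to 25483573, apart from P5 CD11c+ replicate 2 with 2619610. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 28.29 to 243.9, so none was a duplicate of another. For genes with few counts, a ratio is given with its exact 95% interval, and where the lower group had 0 counts the fold is a bound against a floor of 3 counts over the group. These intervals and floors cover counting error only, since the reads carry no molecular identifiers.

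The choices that follow were made before the data were examined, except where stated. Each age was fitted on its own libraries with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filtering with filterByExpr and scaling with trimmed means of M-values (TMM). The difference between ages was tested as an interaction term in a fit of all 10 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05, and every adjusted p given for a gene is from this test. Fold changes are log2 values of CD11c+ over CD11c−, with a standard error (SE) from the fold change and its F statistic. Group levels are TMM-scaled CPM (counts scaled to the library total), given as mean ± SD over libraries, and values of single libraries are plain CPM computed from the deposited counts.

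Genes were named by a fixed rule. It took Itgax and 12 microglial genes (Igf1, Spp1, Clec7a, Lpl, Apoe, Trem2, P2ry12, Tmem119, Cx3cr1, Sall1, Tnf and Il1b), then the 6 largest positive and 6 largest negative fold changes past the threshold. Those had to have an average log2 CPM of at least 3 and no overlap between groups. For the difference between ages the 5 largest in each direction were taken. From each gene list up to 4 members with the smallest p were taken. The 28 gene lists held 845 members, of which 838 were matched to a gene, 2 of them through an older symbol, and 7 were not matched. The 27 lists with at least 5 tested members that were tested covered microglial states, immune functions, metabolism, stress, and markers of other cell types. The remaining list, of Y-linked genes and Xist, served only to check the sex of the samples. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Camera compares the genes of a list with all other genes.

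Each test was checked on simulated counts in which 200 genes had been changed. Changed genes and list members were drawn only from genes above a minimum mean level, so recovery of weaker genes was not measured. At P5 (15410 genes) 1.47% of 2-fold, 16.7% of 4-fold and 83.3% of 32-fold changes were recovered, with 3 false calls. Without P5 CD11c+ replicate 2 (15841 genes) the shares were 50%, 97% and 100%, with 22 false calls. At 9 months (15740 genes) they were 38.2%, 98.5% and 100%, with 12 false calls. For the difference between ages (19555 genes) they were 0%, 1.52% and 97%, with 4 false calls. No simulated change was called in the wrong direction (0 in each). A list of 30 genes shifted 2-fold passed in all 4 simulations, with camera p between 1.19e-38 and 1.75e-11. Genes were simulated independently of each other, so this does not check camera where genes of a list are correlated. Camera gave lists left unchanged a p between 0.0317, in the simulation of the adult comparison, and 0.998.

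Alternatives were DESeq2 size factors, no filter, a filter of 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a fit of all 10 libraries for the within-age tests, the replicate number as a block, a minimum fold, and each library left out in turn. After the data were seen, scaling to the homeostatic microglia list was added, in which library factors were set so that this list had a median deviation of 0, alone and with P5 CD11c+ replicate 2 left out. It moved the fold changes by 0.924 at P5, by 0.384 at P5 without that replicate, by -1.2 at 9 months and by -2.17 for the difference between ages, on the log2 scale. The size factors of DESeq2 moved the difference between ages by -0.223. Correlations between libraries were computed on log2(CPM + 1) over 17202 genes with a mean above 1 CPM. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.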

Results

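RNA-seq counts were analysed for CD11c+ and CD11c− microglia of wild-type mice at P5, during early postnatal brain development, and at 9 months, in the adult. The question, as the design states it, was how the CD11c+ subset differs from the CD11c− subset at each age. At P5 the CD11c+ libraries held 15181698, 2619610 and 18707050 counts and the CD11c− libraries 14841417, 13562130 and 11892082. At 9 months they held 25483573 and 23400998 against 24140297 and 22122354. Xist and the Y-linked Ddx3y were both detected in all 10 libraries, at 29.8 to 563 CPM and 37.1 to 333.6 CPM, so no library showed RNA of a single sex alone. Across genes, P5 CD11c+ replicate 2 correlated with the other 5 P5 libraries at r = 0.627 to 0.697, whereas those 5 correlated with each other at 0.947 to 0.993. It had 23033 genes at 1 CPM or more, against 12762 to 14735 in the other libraries, and 10.8% of its counts lay in long non-coding, unclassified and pseudogene transcripts. It was kept, and the main P5 results are also given without it.

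At P5 the genes that rose in CD11c+ cells were led by markers of border-associated macrophages, the macrophages of the meninges, perivascular spaces and choroid plexus. Cd209f, a C-type lectin (ENSMUSG00000051906, chromosome 8, 4102787 to 4105835), had 87.8 ± 34.8 CPM against 0.564 ± 0.405 (SD, n = 3 each), a log2 fold change of 7.31 ± 0.66 (SE; edgeR adjusted p = 0.018). Pf4, the chemokine platelet factor 4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383), rose by 6.34 ± 0.63 (edgeR adjusted p = 0.0231). The haemoglobin scavenger receptor Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) rose by 6.12 ± 0.64 (edgeR adjusted p = 0.0274), and the hyaluronan receptor Lyve1 by 5.98 ± 0.65 (edgeR adjusted p = 0.0302), with 941 ± 181 CPM against 14.9 ± 10.7. The lectin ficolin A gene Fcna rose by 5.38 ± 0.39 (edgeR adjusted p = 0.0179) and the receptor phosphatase Ptprk by 5.14 ± 0.46 (edgeR adjusted p = 0.018).

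Of 15410 genes tested at P5, 46 rose in CD11c+ cells and 0 fell, all 46 by at least 2-fold. At an unadjusted p under 0.05, 668 were higher and 409 lower. DESeq2 called 392 up and 162 down, and limma-voom 75 up and 0 down. The common coefficient of variation between replicates was 0.614, and 0.243 without CD11c+ replicate 2. Without that library 801 genes rose and 700 fell, and these included all 46; with the scaling to the homeostatic list added, 2144 rose and 507 fell. With any other P5 library left out, edgeR called 0 genes.

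Of the 27 border-associated macrophage markers tested, 11 rose at P5 and 16 did not pass, and 22 rose when adjusted over the list alone. In 23 of them every CD11c+ library exceeded every CD11c− library, which chance gives for 5% of genes. The endocytic adaptor Dab2 had 2658 against 164 CPM and rose by 4.02 ± 0.34 (edgeR adjusted p = 0.0179), the carbonyl reductase Cbr2 rose by 5.06 ± 0.43 and the ferroxidase ceruloplasmin gene Cp by 2.87 ± 0.22 (both edgeR adjusted p = 0.0179). The mannose receptor Mrc1, with 3109 against 306 CPM, had a fold change of 3.35 and did not pass (edgeR adjusted p = 0.0525). The median of the list was 3.91 (camera adjusted p = 1.1e-80), and the call held with an estimated correlation (adjusted p = 0.0319). Without CD11c+ replicate 2, 24 of the 27 rose and the median was 4.03, with adjusted p = 0.0699 with an estimated correlation. The list took 2.23%, 1.63% and 1.92% of counts in the CD11c+ libraries and 0.303%, 0.256% and 0.179% in the CD11c− libraries.

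None of the 13 microglial genes fixed for the comparison passed at P5. Itgax itself (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657), which encodes the sorted protein, had 250.2, 49.2 and 144.8 CPM in the CD11c+ libraries and 33.1, 61.9 and 29.4 CPM in the CD11c− libraries, a fold change of 1.63 ± 0.61 (edgeR adjusted p = 0.622). The growth factor Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) had 451 ± 66.0 against 95.8 ± 28.6 CPM, a fold change of 2.24 ± 0.33 (edgeR adjusted p = 0.0724). The osteopontin gene Spp1 was at 2.04 ± 0.52 (edgeR adjusted p = 0.273), the lipid carrier Apoe at 1.26 ± 0.45 (edgeR adjusted p = 0.572) and the microglial surface protein Tmem119 at -2.05 ± 0.62 (edgeR adjusted p = 0.415). Without CD11c+ replicate 2 these 5 passed in the same direction, Itgax at 2.06 (adjusted p = 0.0222), Igf1 at 2.15 (0.00525), Spp1 at 2.27 (0.0277), Apoe at 1.54 (0.023) and Tmem119 at -1.59 (0.0298). The other fixed genes passed neither way. The lectin Clec7a was at 0.53, the lipase Lpl at 1.42, the lipid receptor Trem2 at -0.73, the purinergic receptor P2ry12 at -1.16, the fractalkine receptor Cx3cr1 at 0.30, the transcription factor Sall1 at -1.23, and the cytokines Tnf and Il1b at 0.27 and -0.53. Without replicate 2, Cx3cr1 and Tnf changed sign, to -0.54 and -0.33. Lpl had 2957 CPM in replicate 2 against 681 and 622 in the other CD11c+ libraries and stood at 0.29 without it. Trem2, P2ry12 and Sall1 then stood at -0.32, -0.76 and -0.76.

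The lists of microglial states and functions moved by less at P5, and no call among them held with an estimated correlation. The 36 homeostatic microglia genes, which mark resting microglia, had a median of -0.61 (camera adjusted p = 9.2e-08, adjusted p = 0.463 with an estimated correlation), with 0 members passing and 1 lower when adjusted over the list alone. The list of 44 disease-associated microglia genes, led by Igf1, Nrp1 and Atp6v0d2, was at 0.30 (0.0105, and 0.573 estimated), with 1 member higher over the list alone. That of 34 genes of microglia in neonatal axon tracts was at 0.65 (1.5e-06, and 0.463 estimated). Its member Colec12, a scavenger receptor also on the border-associated list, rose by 4.82 ± 0.51 (edgeR adjusted p = 0.0282), and 7 were higher adjusted over the list alone. Type I interferon response genes were at 0.53 (5.1e-07, and 0.463 estimated), with 0 of 43 passing and 5 over the list alone, among them the helicase Ddx60 at 2.02 (edgeR adjusted p = 0.0551). Complement and phagocytic receptor genes were at 0.20 (0.000315, and 0.463 estimated), with 0 of 37 passing and 9 up and 1 down over the list alone, and C4b at 2.73. MHC class II genes, which present antigen, were at 0.50 (0.00395, and 0.541 estimated), with 1 of 15 higher over the list alone, and H2-Ab1 at 2.47 (edgeR adjusted p = 0.387).

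Lipid uptake, storage and efflux genes were at 0.29 (camera adjusted p = 0.0466, and 0.573 estimated), with 3 up and 1 down of 31 over the list alone, and S phase genes at -0.19 (0.0177, and 0.463 estimated), with 0 of 44. Those not passing were growth and neurotrophic factors at 0.31 (0.0589; 5 of 31 higher over the list alone, Bmp2 at 5.06), pro-inflammatory cytokines and chemokines at 0.19 (0.0539), MHC class I presentation at 0.22 (0.0612), G2 and M phase at -0.06 (0.527), cholesterol synthesis at 0.19 (0.465), lysosome at 0.11 (0.151) and glycolysis at -0.12 (0.0998). Immediate-early and dissociation stress genes had a median of -0.10, a mean of 0.16 and an upward test (0.815). Single members that rose were the chemokine Ccl7 by 4.32 ± 0.27 (edgeR adjusted p = 0.0179), the lysosomal sulfamidase Sgsh by 1.98 ± 0.26 (0.0479) and the matricellular Ccn1 by 4.43 ± 0.49 (0.0302).

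Without CD11c+ replicate 2 more members of these lists passed over all genes, though no list held with an estimated correlation. They were 10 up of 46 disease-associated genes (median 0.52), 12 up of 34 axon tract genes, 13 up of 43 interferon genes, 12 up and 1 down of 37 complement genes (median 0.49), 6 up of 15 MHC class II genes, 6 up and 2 down of 32 lipid genes, and 2 up and 7 down of 36 homeostatic genes. Several of these list calls depended on a library. The disease-associated call ended without CD11c+ replicate 1 (camera adjusted p = 0.248), CD11c+ replicate 3 (0.189) or CD11c− replicate 1 (0.0611), and the lipid call without the same libraries (0.417, 0.208 and 0.0974). The MHC class II call ended without CD11c+ replicate 3 (0.204), and the S phase call without CD11c+ replicate 2 (0.053) or CD11c− replicate 1 (0.194). Scaling to the homeostatic list, which moved all fold changes up together by 0.924 and was not tested per list, turned the S phase median to 0.77 and set that of the homeostatic list at 0.26; the disease-associated and axon tract medians were then 1.09 and 1.4. Without CD11c+ replicate 2 the lysosome list passed at 0.45 (1.66e-06, and adjusted p = 0.545 with an estimated correlation), with 10 of its genes rising, and the growth factor list, not passing either way, stood at -0.23.

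Markers of other cells and of RNA makeup differed between the same P5 libraries. Mitochondrially encoded transcripts made up 2.39%, 0.791% and 2.80% of counts in CD11c+ libraries and 7.19%, 20.8% and 28.1% in CD11c− libraries. All 13 were lower in every CD11c+ library than in every CD11c− library. Their estimated correlation was 0.921, so they count as little more than 1 observation, which chance separates this way 5% of the time. Their median was -3.40 (camera adjusted p = 5e-27, adjusted p = 0.249 with an estimated correlation). Over all genes 0 passed (13 without CD11c+ replicate 2), and 13 passed when adjusted over the list alone. Neutrophil markers had a median of -3.34 (1.76e-31, and 0.249 estimated), also -3.34 with the 1 member at 0 counts set to its bound, and 0 of 24 passed over all genes (19 without CD11c+ replicate 2) and 19 over the list alone. Monocyte markers were at -1.02 (9.2e-08, and 0.463 estimated), with 3 of 25 lower over the list alone, including Ly6c2 at -3.30. Dendritic cell markers were at 1.46 (1.54e-08, and 0.153 estimated), where the lectin Clec10a rose by 4.54 ± 0.55 (edgeR adjusted p = 0.0412) and the transcription factor Irf4 by 2.29 ± 0.29 (0.0431), and 5 of 23 were higher over the list alone (6 rose over all genes without CD11c+ replicate 2). Vascular markers were at 0.37 (0.0466, and 0.463 estimated), with Egfl7 up by 3.29 ± 0.29 (edgeR adjusted p = 0.018), and erythroid markers at -1.0 (0.0316, and 0.579 estimated), or 0.23 when scaled to the homeostatic list.

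The vascular call ended without CD11c+ replicate 2 (median -0.36, camera adjusted p = 0.877), CD11c− replicate 1 (0.221) or CD11c− replicate 2 (0.0626). The erythroid call ended without CD11c+ replicate 1 (0.248) or 2 (0.189), and without CD11c− replicate 3 the median was 0.09. Oligodendrocyte lineage markers at 1.33 (0.103) and astrocyte markers at 0.58 (0.527) did not pass. Neuron markers had a median of 0.56 and a mean of 0.42 but a downward test (0.108), and lymphocyte markers a median of 0.34 and a downward test (0.808). Without CD11c+ replicate 2 neuron markers passed at -2.17 (2.37e-10, and adjusted p = 0.405 with an estimated correlation), with 16 of 30 falling, and astrocyte markers at -0.95 (0.0427, and 0.731 estimated). Oligodendrocyte and lymphocyte medians then turned to -0.74 (0.969) and -0.14 (0.785), neither passing.

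**Figure D1:**
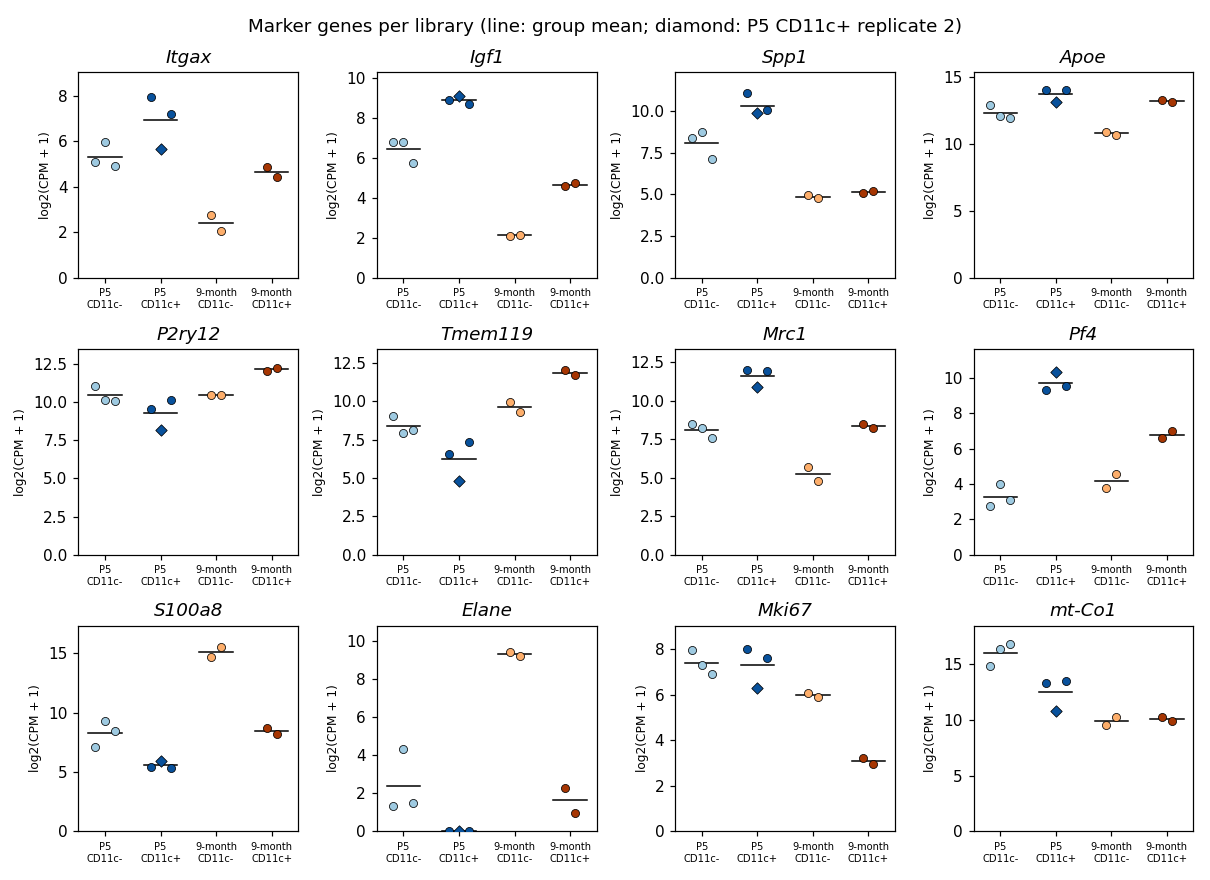
Level of 12 genes in each library, as log2(CPM + 1) on the vertical axis, by age and subset; points are libraries, lines are means of the log2 values and the diamond is P5 CD11c+ replicate 2. Mrc1 and Pf4 stood higher in every CD11c+ library than in every CD11c− library of the same age, S100a8 and Elane lower, and the group means of P2ry12 and Tmem119 were lower in CD11c+ libraries at P5, where neither passed the test, and higher at 9 months.

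At 9 months several microglial genes were higher in the CD11c+ libraries and the neutrophil granule genes Elane and Mpo were lower. A lower share of microglial RNA in the CD11c− libraries would also make microglial genes higher in CD11c+. Summed RNA does not tell this from a change within microglia. Itgax rose by 2.08 ± 0.33 (SE; edgeR adjusted p = 0.00397), with 21.4 ± 4.82 CPM against 5.06 ± 1.65 (SD, n = 2 each). Igf1 rose by 2.46 ± 0.27 (edgeR adjusted p = 0.000801), and Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) by 2.04 ± 0.15 (edgeR adjusted p = 0.000148), with 8282 against 2015 CPM. Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516) rose by 1.85 ± 0.21 (edgeR adjusted p = 0.00102) and P2ry12 by 1.29 ± 0.15 (0.00107). Neutrophil elastase, Elane (ENSMUSG00000020125, chromosome 10, 79886312 to 79888216), fell by 8.41 ± 0.57 on the log2 scale, with 2.12 against 727 CPM (edgeR adjusted p = 0.000108), and myeloperoxidase, Mpo, fell by 8.38 ± 0.71 (0.000286).

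Among the other fixed genes, Trem2 rose by 1.20 ± 0.16 (edgeR adjusted p = 0.00192), Cx3cr1 by 1.32 (0.00352), Sall1 by 1.30 (0.00197) and Tnf by 0.79 ± 0.16 (0.0107). Clec7a fell by 1.14 ± 0.19 (0.00474), and Il1b, with 75.9 against 535 CPM, fell by 2.82 ± 0.16 (5.88e-05). The CD11c− libraries also held more neutrophil and monocyte marker RNA, given below. Decreases in this paragraph therefore cannot be assigned to microglia, with or without the scaling that follows. Spp1 at -0.09 ± 0.18 (0.745) and Lpl at 0.34 (0.199) did not pass. When libraries were scaled to the homeostatic list, Itgax stood at 0.86 and missed the threshold (0.0644), Igf1 at 1.26 (0.00784), Apoe at 0.83 (0.00254) and Tmem119 at 0.64 (0.0355) still passed, as did Clec7a and Il1b, and Trem2 and Tnf turned to -0.01 and -0.42. P2ry12 at 0.09 (0.643), Cx3cr1 at 0.11 (0.651) and Sall1 at 0.09 (0.696) did not pass under this scaling, which holds their own list, the homeostatic genes with Tmem119 among them, near 0 by construction, and Spp1 at -1.29 (0.00122) and Lpl at -0.86 (0.00824) passed as lower. In the fit of all 10 libraries, which shares the spread of the P5 samples, only Igf1 (adjusted p = 0.00531) and Apoe (0.0468) of the fixed genes passed. Itgax (0.118), Tmem119 (0.165), Il1b (0.0777), Trem2 (0.267), P2ry12 (0.26), Cx3cr1 (0.21), Sall1 (0.321), Tnf (0.457) and Clec7a (0.309) lost their calls there.

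Of 15740 genes tested at 9 months, 2333 rose and 2869 fell, 1394 and 2326 of them by at least 2-fold. The count was 1158 (280 up, 878 down) in the fit of all 10 libraries, and 8859 (132 up, 8727 down) when scaled to the homeostatic list, which moved the median of all genes to -1.18. The largest increases included lectins of the Cd209 family, which border-associated macrophages express. Cd209b rose by 4.37 ± 0.35 (edgeR adjusted p = 0.000214), Cd209f by 4.22 ± 0.28 (9.99e-05), the secreted phospholipase Pla2g2d by 4.12 ± 0.54 (0.00179), Cd163 by 4.06 ± 0.32 (0.00022) and the complement component C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) by 3.53 ± 0.19 (5.25e-05). The monocyte receptor Cd300e rose by 3.75 ± 0.37 (0.000526), with adjusted p = 0.0885 in the fit of all 10 libraries. The largest decreases under the rule for named genes, which asks for an average log2 CPM of at least 3, were in Ear6, Prg3, Prg2, Epx, Elane and Mpo. Prg2, the eosinophil major basic protein, fell by 10.11 ± 0.79, with 0.944 against 1064 CPM (0.000197). Ear6, a member of a family of near-identical ribonucleases, had 3 counts in the CD11c+ libraries and 5107 in the CD11c− libraries, a ratio of 1.8e+03 (exact 95% interval 615 to 8.73e+03), and Prg3 had 1 and 1927 counts, a ratio of 2.04e+03 (365 to 8.05e+04). Eosinophil peroxidase, Epx, had 5 and 3936 counts, a ratio of 832 (356 to 2.56e+03).

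Of the 36 homeostatic microglia genes, 32 rose and 2 fell at 9 months, and 33 and 2 when adjusted over the list alone, with a median of 1.27 (camera adjusted p = 6.33e-15, adjusted p = 0.202 with an estimated correlation). Fcrls rose by 1.95 (edgeR adjusted p = 0.000226) and the growth factor receptor Csf1r by 1.89 (0.000312). The list took 11% and 10.8% of counts in CD11c+ libraries and 4.12% and 3.87% in CD11c− libraries. A lower share of microglial RNA in the CD11c− libraries cannot be told from a change within microglia. Lysosome genes followed, with 38 of 57 rising and 3 falling (40 and 4 over the list alone), a median of 1.04 (2.45e-09, and 0.3 estimated) and the protease Ctsb up by 1.52. MHC class II genes had 12 of 15 rising and 0 falling (12 and 1 over the list alone), a median of 1.04 (6.67e-05, and 0.349 estimated), H2-Ab1 up by 1.16 and the costimulator Cd86 up by 1.47. Complement and phagocytic receptor genes had 24 of 36 rising and 10 falling over all genes and over the list alone, with a median of 0.94 (0.000735, and 0.349 estimated); the receptor Mertk rose by 1.66 and C3 fell by 4.99. Immediate-early and dissociation stress genes were at 0.40 (0.0197, and 0.3 estimated), with 15 of 40 rising and 4 falling (19 and 4 over the list alone), and this call ended without CD11c− replicate 1 (camera adjusted p = 0.0589), with the 5 CPM filter (0.055) and in the fit of all 10 libraries (0.147). Scaled to the homeostatic list, the lysosome, MHC class II, complement and stress medians turned negative, at -0.16, -0.16, -0.26 and -0.80, and the homeostatic median was 0.07. In the fit of all 10 libraries Fcrls (edgeR adjusted p = 0.076), Csf1r (0.143), Ctsb (0.0849), H2-Ab1 (0.409) and Cd86 (0.0648) did not pass.

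Proliferation and glycolysis genes were lower in the 9-month CD11c+ libraries. The CD11c− libraries also held more neutrophil and monocyte marker RNA, given below. Summed RNA does not tell which cells a transcript came from, so these differences cannot be assigned to microglia. Of 48 G2 and M phase genes, 46 fell and 0 rose, over all genes and over the list alone, with a median of -3.09 (camera adjusted p = 2.81e-42, adjusted p = 0.202 with an estimated correlation). The topoisomerase Top2a fell by 3.26 (edgeR adjusted p = 4.61e-05) and the proliferation marker Mki67 by 3.42. Of 44 S phase genes 33 fell and 1 rose (35 and 2 over the list alone), with a median of -1.66 (2.03e-10, and 0.3 estimated), and the ribonucleotide reductase subunit Rrm2 fell by 4.38. Of 26 glycolysis genes 15 fell and 4 rose (15 and 6 over the list alone), with a median of -1.01 (0.000735, and 0.349 estimated), and the glucose transporter Slc2a3 fell by 4.54. In the same libraries 23 of 24 neutrophil markers fell and 0 rose, over all genes and over the list alone, with a median of -7.11 (1.06e-66, and 0.202 estimated), or -7.07 with the 2 members at 0 counts set to their bound. The alarmin S100a8 had 317 against 43402 CPM and fell by 7.10, and Ngp fell by 6.47. These markers took 0.324% and 0.226% of counts in CD11c+ libraries and 14.5% and 19.5% in CD11c− libraries. Of 25 monocyte markers 20 fell and 2 rose (20 and 3 over the list alone), with a median of -4.19 (2.66e-28, and 0.22 estimated).

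Of 27 border-associated macrophage markers, 19 rose and 5 fell at 9 months over all genes and over the list alone, with a median of 2.01 (camera adjusted p = 2.45e-09, adjusted p = 0.202 with an estimated correlation) and 0.81 when scaled to the homeostatic list. Lyve1 rose by 3.29 (edgeR adjusted p = 0.000133) and Cbr2 by 2.91 (6.79e-05), while Clec12a fell by 3.14 (5.16e-05). The markers took 0.318% and 0.324% of counts in CD11c+ libraries and 0.182% and 0.159% in CD11c− libraries. Dendritic cell markers were at 1.15 (0.0461, and 0.349 estimated), with 13 of 26 rising and 3 falling (14 and 3 over the list alone) and Cd209a up by 2.93 (adjusted p = 0.126 for Cd209a in the fit of all 10 libraries), and the list call ended without CD11c+ replicate 1 (camera adjusted p = 0.134) or 2 (0.0883), and with the 5 CPM filter (0.214). Its median was -0.05 when scaled to the homeostatic list.

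The remaining lists did not pass with camera at 9 months. With fry, axon tract genes (adjusted p = 0.0105), growth factors (0.0423), MHC class I (0.0184) and cholesterol synthesis (0.00868) did pass. Disease-associated genes were at 0.07 (camera adjusted p = 0.247), with 16 of 44 rising and 10 falling (17 and 11 over the list alone); the galectin Lgals3 fell by 3.87 and Igf1 and Apoe rose. Axon tract genes were at -0.09 (0.238), with 14 rising and 14 falling of 35, interferon response genes at -0.02 (0.352), with 8 and 11 of 43, cytokines and chemokines at 0.33 (0.346), with 12 and 9 of 37, and growth factors at 1.07 (0.0946), with 10 and 4 of 27. Scaled to the homeostatic list these became 4 up and 25 down for disease-associated genes (median -1.14), 5 and 21 for axon tract (-1.29), 0 and 33 for interferon (-1.23), 1 and 23 for cytokines (-0.88) and 2 and 9 for growth factors (-0.15). MHC class I was at 0.23 (0.128), cholesterol synthesis at -0.31 (0.679), lipid handling at 0.26 (0.643), lymphocytes at -0.40 (0.297), neurons at 0.39 (0.65), astrocytes at 0.42 (0.17) and erythroid genes at -0.31 (0.887). Under that scaling MHC class I had 0 up and 15 down (-0.97), cholesterol synthesis 0 and 18 (-1.52) and lipid handling 2 and 18 (-0.94). Over all 15740 genes 132 rose and 8727 fell under it, so decreases were general. The CD11c− libraries also held more neutrophil and monocyte marker RNA, so decreases in these lists cannot be assigned to microglia. Vascular markers had a median of 0.83 and an upward test but a mean of -0.31 (0.887). Median and test differed in sign for oligodendrocyte markers, at -0.76 with an upward test, and the 13 mitochondrially encoded transcripts, at -0.28 with an upward test and 0 passing.

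**Figure D2:**
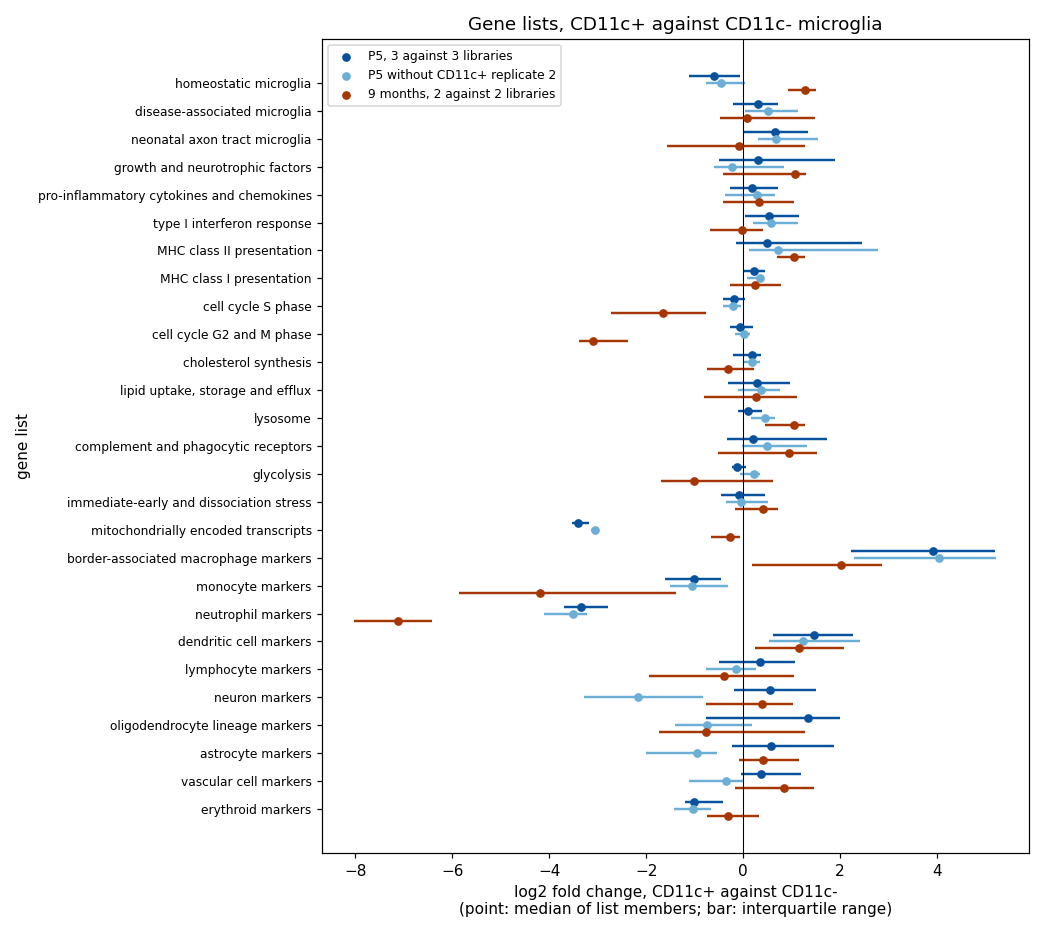
Log2 fold change of CD11c+ over CD11c− libraries on the horizontal axis for 27 gene lists on the vertical axis; points are medians over list members and bars the interquartile range, at P5, at P5 without CD11c+ replicate 2, and at 9 months. Border-associated macrophage markers lay at 3.91, 4.03 and 2.01 and neutrophil markers at -3.34, -3.51 and -7.11; homeostatic microglia genes lay at -0.61, -0.45 and 1.27 (0.26 at P5 and 0.07 at 9 months when scaled to that list).

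The difference between ages of the CD11c+ to CD11c− fold change passed for 364 of 19555 genes, with 59 more positive at 9 months and 305 more negative; the SMART-Seq kit is stated for the 9-month libraries only, so library preparation may have changed together with age. Adgrg1, an adhesion receptor on the homeostatic list (ENSMUSG00000031785, chromosome 8, 94974751 to 95014217), had within-age folds of -1.62 at P5 and 1.76 at 9 months, a difference of 3.55 ± 0.70 (SE, 6 and 4 libraries; edgeR adjusted p = 0.0369). The collagen receptor Mrc2 differed by 3.77 ± 0.66 (edgeR adjusted p = 0.0247), Tmem44 by 3.90 ± 0.71 (0.0267), the organic anion transporter Slco4a1 by 3.43 ± 0.66 (0.0335) and Asap3 by 3.40 ± 0.61 (0.0264). Scaled to the homeostatic list, the 9-month folds were 0.56 for Adgrg1 (edgeR adjusted p = 0.0359) and 0.45 for Mrc2 (0.189). That scaling moved differences between ages by -2.17 in the median over genes, so the size of these positive differences depends on it. The kinase Stk39 (ENSMUSG00000027030, chromosome 2, 68210445 to 68472268) had folds of 3.02 at P5 and -5.61 at 9 months, a difference of -8.28 ± 0.81 (edgeR adjusted p = 0.012). Stk39 stood at 27.49 CPM in P5 CD11c+ replicate 2, against 8.30 and 7.91 in replicates 1 and 3. Prkar2b, Cpne2, the lipopolysaccharide-binding protein gene Lbp and Crispld2 differed by -7.64, -7.22, -6.60 and -6.52. In P5 CD11c+ replicate 2 Prkar2b stood at 24.05 CPM (4.61 and 6.47 in replicates 1 and 3). Lbp stood there at 29.01 (8.43 and 5.77), Crispld2 at 23.29 (5.07 and 4.81) and Cpne2, lower, at 5.73 (13.17 and 14.91). In the 9-month CD11c− libraries Prkar2b stood at 23.1 and 38.6 CPM, against 0.314 and 0.342 in CD11c+. Cpne2 stood at 151 and 119 (2.47 and 3.63), Lbp at 79.1 and 64.9 (1.18 and 1.62) and Crispld2 at 155 and 98.9 (2.47 and 1.37). Those CD11c− libraries also held more neutrophil and monocyte marker RNA, so these differences cannot be assigned to microglia. None of the 13 fixed genes passed, with Tmem119 at 4.04 (edgeR adjusted p = 0.0722), P2ry12 at 2.59 (0.166), Spp1 at -1.95 (0.234), Apoe at 0.94 (0.537), Itgax at 0.59 (0.795) and Igf1 at 0.45 (0.685).

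Among the lists, 10 differed between ages. Homeostatic microglia genes had a median difference of 2.22 (camera adjusted p = 5.1e-16, adjusted p = 0.339 with an estimated correlation) and 0.20 when scaled to that list, and 4 of 36 passed. Lysosome genes were at 0.83 (0.000316, and 0.899 estimated), turning to -1.06 under that scaling, and mitochondrially encoded transcripts at 2.98 (1.09e-08, and 0.414 estimated). G2 and M phase genes were at -2.87 (1.2e-60), with 22 of 48 passing, and held with an estimated correlation (adjusted p = 0.0354). Like the 9-month difference in these genes, this cannot be assigned to microglia from summed RNA. S phase genes at -1.19 (7.74e-12, and 0.242 estimated), neutrophil markers at -3.56 (9.1e-22, and 0.242 estimated), monocyte markers at -2.51 (7.83e-12, and 0.414 estimated), border-associated macrophage markers at -2.10 (1.8e-11, and 0.299 estimated), interferon genes at -0.72 (0.000892, and 0.899 estimated) and axon tract genes at -0.54 (0.00102, and 0.875 estimated) were also lower. Scaled to the homeostatic list the medians were 1.29 for mitochondrial transcripts, -5.03 for G2 and M phase, -3.49 for S phase, -5.78 for neutrophils, -4.66 for monocytes, -4.01 for border-associated macrophages, -2.65 for interferon and -2.81 for axon tract genes. Without P5 CD11c+ replicate 2 the count of genes was 3496 (1607 and 1889). Scaled to the homeostatic list, 15 were more positive and 5178 more negative, or 190 and 8064 with that replicate also left out, and edgeR called 0 genes when any 9-month library, or P5 CD11c− replicate 3, was left out. At an unadjusted p under 0.05 the full set of libraries gave 1318 and 1833 genes, and DESeq2 called 2385.

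Genes called up at both ages numbered 26, of 44 called at P5 and 2290 at 9 months among 13709 genes tested at both, against 7.35 from independent lists (one-sided Fisher's exact test, p = 2.51e-10; genes are not independent replicates). They were Blvrb, Cbr2, Ccl24, Ccl7, Ccn1, Cd163, Cd209f, Cd38, Clec10a, Colec12, Cp, Dab2, Ednrb, Fcna, Gprc5c, Irf4, Itsn1, Lyve1, Pf4, Pomk, Ptprk, Sema6d, Sh3bgrl2, Spats2l, Tmem106a and Trpv4, of which 10 stand on the border-associated list. With no gene called down at P5, 0 fell at both ages, and 2 were up at P5 and down at 9 months, against 8.1 from independent lists. Across genes the fold changes of the ages correlated at r = 0.157 and rho = 0.0508, and at r = 0.3 without P5 CD11c+ replicate 2. Without that library 269 genes rose at both ages (expected 124, one-sided Fisher's exact test, p = 5.81e-40), among them Igf1 at 2.15 and 2.46, Itgax at 2.06 and 2.08, Apoe at 1.54 and 2.04 and C4b at 3.05 and 3.53. In the same setting 101 fell at both (expected 88.5, p = 0.0768, one-sided Fisher's exact test).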

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

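The tests on the neutrophil and border-associated macrophage patterns were chosen after the results were seen.

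The CD11c+ to CD11c− difference changed with age for 364 genes by the interaction test of edgeR (3496 without P5 CD11c+ replicate 2, and 0 without P5 CD11c− replicate 3 or any 9-month library). The differences named in the report, as 9 months minus P5 on the log2 scale, were 3.90 for Tmem44, 3.77 for Mrc2, 3.55 for Adgrg1, 3.43 for Slco4a1 and 3.40 for Asap3. On the negative side they were -8.28 for Stk39, -7.64 for Prkar2b, -7.22 for Cpne2, -6.60 for Lbp and -6.52 for Crispld2. As median differences, homeostatic microglia genes stood at 2.22, lysosome genes at 0.83 and mitochondrially encoded transcripts at 2.98. The axon tract list stood at -0.54, interferon response at -0.72, S phase at -1.19, G2 and M phase at -2.87, border-associated macrophages at -2.10, monocytes at -2.51 and neutrophils at -3.56. Scaling to the homeostatic list moved differences by -2.17 in the median over genes, and the lysosome difference turned to -1.06. Summed RNA does not assign the negative differences to microglia. The labels state the SMART-Seq kit for the 9-month libraries only, so age and library preparation cannot be told apart for any of these differences.

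Neutrophil genes were higher in the 9-month CD11c− libraries, where S100a8 reached 26590 and 48020 CPM and Ngp 31740 and 42250 CPM. A lower share of microglia alone would raise every other cell type alike. Border-associated macrophage markers moved the other way, with a median of 2.01 against a half-width of their interquartile range of 1.34. Scaled to the homeostatic list that median was 0.81, below the half-width, with 14 up and 8 down. Monocyte and lymphocyte markers, at -4.19 and -0.40, moved towards CD11c−. The bound on the border-associated list was therefore met only without that scaling. The lists did not move alike under either scaling. Neutrophil markers had a median of -7.11 (interquartile range -8.02 to -6.41), and -8.32 when scaled. Border-associated markers had an interquartile range of 0.187 to 2.87, and their median stayed above 0 when scaled. For these lists, the values argue against a lower share of microglia alone. Neutrophils or their precursors among the sorted CD11c− cells stay open as a hypothesis: 95.8% of the tested neutrophil markers passed towards CD11c−, but this restates the pattern and cannot favour an explanation. In CD11c+ libraries 14 of the 24 listed genes also reached 10 CPM, and 1 stands on another list. The list took 0.324% and 0.226% of counts there, against 14.5% and 19.5% in CD11c− libraries. A gate removing granulocytes is not given in the sources used here. Expression by CD11c− microglia predicted that homeostatic genes would not be lower in the CD11c− libraries. They were lower there, with a list median of 1.27 and 4.12% and 3.87% of counts against 11% and 10.8%. The prediction was not met, but it was written after these values were seen, so it cannot count against the explanation. Summed RNA does not tell which cell a transcript came from, so the explanation is not excluded.

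Border-associated macrophage genes were higher in the P5 CD11c+ libraries, where Mrc1 was at 4080, 1904 and 3889 CPM and Stab1 at 6805, 2211 and 4642 CPM. The divergent replicate 2 alone is argued against, because the list median was 4.03 without it. Border-associated macrophages among the sorted CD11c+ cells stay open as a hypothesis: 85.2% of the tested markers had every CD11c+ library above every CD11c− library (chance gives this for 5% of genes), but this restates the pattern and cannot favour an explanation. Of the 28 listed genes, 15 also reached 10 CPM in CD11c− libraries and 4 stand on another list, and a gate removing these macrophages is not given in the sources used here. Expression by CD11c+ microglia themselves stays open as well, since summed RNA does not tell cells apart (homeostatic list median -0.609).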

How the results depend on the processing

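The scalings to the homeostatic list were chosen after the data were seen; all other alternatives were set beforehand. At P5 the 46 genes became 117 with the 5 CPM filter, 554 with DESeq2, 75 with limma-voom, 138 in the fit of all 10 libraries, 2651 with the scaling to the homeostatic list and replicate 2 left out, and 0 to 1501 with a library left out. At 9 months the 5202 genes became 1158 in the fit of all 10 libraries and 8859 under that scaling, and 4006 to 6087 with a library left out, where a lone sample was assumed to vary like the others. The 364 interaction genes became 623 with DESeq2 size factors, 693 without a filter, 1192 with the 5 CPM filter, 2385 with DESeq2, 5193 when scaled, 8254 when scaled with replicate 2 left out, and 0 to 3496 with a library left out. The 26 genes called in the same direction at both ages, all up, became 53 (52 up), 199 (146 up) and 40 (all up) with the 5 CPM filter, DESeq2 and limma-voom, 61 (36 up) in the fit of all 10 libraries, 743 (667 up) when scaled with replicate 2 left out, and 0 to 370 (269 up) with a library left out. The correlation of 0.157 became 0.0487 without a filter, 0.311 when scaled with replicate 2 left out, and 0.0639 to 0.3 with a library left out. Lists passing went from 15 to 1 (estimated correlation) and 1 (fry) at P5, from 12 to 0 with an estimated correlation at 9 months (16 with fry), and from 10 to 1 and 2 for the interaction. Lists whose test changed direction at P5, with a call in either setting, were astrocytes at -0.952 without CD11c+ replicate 2 (-0.952 to 1.12 with a library left out), immediate-early genes, whose test pointed up, at -0.436 without CD11c+ replicate 3 (-0.436 to 0.0586) and erythroid genes at 0.086 without CD11c− replicate 3 (-1.52 to 0.086). Medians of neuron (0.555 to -2.17) and vascular markers (0.374 to -0.362) also changed sign without CD11c+ replicate 2, while the direction of their tests did not. Scaled to the homeostatic list at 9 months, Lpl reversed to -0.861, Trem2 to -0.0123, Tnf to -0.417, H2-Ab1 to -0.0526, H2-DMb1 to -0.0481, Pdia3 to -0.326, Erap1 to -0.276, H2-Q6 to -0.291, Mfge8 to -0.0635, Fech to -0.0637, Ddx3y to -0.645 and Uty to -0.852. The scaling shift accounts for these; the cause was not tested for the other changes. Of called named genes, 57 of 117 at 9 months, 0 of 16 at P5 and 0 of 10 for the interaction kept direction and call under all alternatives run for them, as did 0 of 12, 1 of 15 and 1 of 10 lists. A further 146 of 4868 values changed sign without passing in either setting. At P5 same-numbered libraries were not consistently alike in their deviations from the group means (r 0.457, 0.095 and -0.403, and up to 0.459 for other pairs). At 9 months, with 2 libraries per group, both same-number values (0.086) are 1 value by construction and cannot decide whether samples are paired. With the replicate number as a block the counts were 0 at P5, 5436 at 9 months, 0 for the interaction and 0 at both ages, with 18, 11 and 10 lists. The 9-month dendritic cell list did not pass with the block (camera adjusted p = 0.0879). Lists were not tested under DESeq2, limma-voom or the scalings to the homeostatic list, nor was the correlation under DESeq2, limma-voom and the fit of all libraries. Depth was lowest in P5 CD11c+ replicate 2, and genes with few counts carry the widest intervals.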

Other observations

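The tests on P5 CD11c+ replicate 2 and on the splits of the P5 libraries were chosen before their results were seen; the genes in the next paragraph were picked after their values were seen.

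Prss34, a serine protease of basophils and mast cells, and Mcpt8, a basophil protease, were lower in CD11c+ cells. At P5 Prss34 did not pass with all libraries (edgeR adjusted p = 0.0828) and passed without CD11c+ replicate 2 (0.00764). It had 0 counts in CD11c+ replicates 1 and 3 and 492 counts in the CD11c− libraries. That is 138-fold lower against a floor of 3 counts over the group, with an exact 95% lower limit of 112-fold. Mcpt8 likewise did not pass with all libraries (0.675), where replicate 2 stood at 3.82 CPM, and passed without it (edgeR adjusted p = 0.00378), with 1 against 647 counts, a ratio of 544 (exact 95% interval 97.3 to 2.15e+04). At 9 months Prss34 fell by 8.15 (edgeR adjusted p = 0.000191) and Mcpt8 by 7.71 (5.66e-05) on the log2 scale. Ttr, the transthyretin gene abundant in choroid plexus, was at 0.329, 1.53 and 0.695 CPM in P5 CD11c+ libraries and 44.5, 5.83 and 11.8 CPM in P5 CD11c− libraries (edgeR adjusted p = 0.142, and 0.0205 without CD11c+ replicate 2). At 9 months it was at 24.9 and 25.1 CPM in CD11c+ and 187 and 174 CPM in CD11c− libraries, and fell by 3.23 (edgeR adjusted p = 3.93e-05).

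P5 CD11c+ replicate 2 stood apart from the other P5 libraries, with 5.27% of counts in ribosomal-RNA-like genes against 0.076% to 1.76% in the other libraries; it shares its group with its replicates, so the design gives no biological explanation to test. Lower depth is argued against, because replicates 1 and 3 thinned to its total still correlated at 0.944 or more with the P5 CD11c− libraries. Reads spread over genes that microglia do not use may contribute, as 44.5% (Wilson 95% interval 41.6 to 47.5) of 1092 olfactory receptor genes had a count, 1.68 times the highest share in another thinned library (26.5%), and the counts in them were 16.4 times the highest. The bound set in advance in favour of this was unsuited, since a share cannot pass 100% and the ratio could reach at most 3.78. The bound set against it, a ratio below 2, was met at 1.68. With that ceiling and the 16.4-fold counts the ratio cannot decide, so this stays open. RNA of other brain cells stays open too: 79.4% of 102 neuron, oligodendrocyte and astrocyte genes exceeded 4 times the median olfactory receptor density, but that median was 0, and the list sums were 4.2, 1.29 and 4.53 times those of replicates 1 and 3. Those sums fell short of the multiple set in advance in favour of this explanation.

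The 6 P5 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 46 genes, the highest of the other 9 gave 0, and 1 split, the real split, gave as many as the real count.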
